A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

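RNA from 6 cultures or samplings of Saccharomyces cerevisiae was measured, 3 arrays of a strain with wild-type TRA1 and 3 of a strain with the tra1-2ts allele, 1 array per strain at 60, 90 and 120 min after a shift from 30 to 37 °C. Per the labels' protocols, total RNA was labelled with biotin by a 3' in vitro transcription kit, which primes on poly(A) tails. The deposited values are on a log2 scale, 1 value per probe set and array; per the submitters' processing notes they come from RMA in the R package oligo, with no version given. RMA corrects the background, makes the distributions of all arrays alike by quantile normalization and summarises the probes of a set per array. It follows that a change of all messenger RNA at once cannot be seen in these values, and that every difference is relative to the bulk of the array. How the probe sets of the table were selected is not stated, and detection calls were not used here.

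Probe sets were named from the platform annotation. Of 6776 probe sets, 5668 name 1 gene, 183 several genes and 925 none, and all 5668 were matched by gene ID to the RefSeq gene table of assembly R64, which was used for symbols and gene order; no coordinates are given because no genome build is named for the array. Control probe sets and those with no or several genes were kept out of the tests. For the 91 genes with more than 1 probe set, the set with the highest mean over the 6 arrays was used. This left 5551 genes, of which 5381 are protein-coding, 91 tRNA, 57 snoRNA and 4 rRNA genes. Suffixes such as _s_at and _f_at mark probe sets that match several related sequences, so values for near-identical copies are uncertain. Columns of other samples in the table numbered 0.

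Tests were run with limma 3.58.1 in R 4.3.3, by linear fits and empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The strain test fitted genotype alone over all 6 arrays and leaves 4 residual degrees of freedom; a smaller set with an absolute log2 difference of at least 1 was counted beside it. The time test fitted genotype and a linear slope over minutes shared by both strains, reported per 60 min. The third test fitted a slope per strain and tested their difference, with 2 residual degrees of freedom. Differences at single times rest on 1 array per strain and were counted without a test. Standard errors are limma's moderated ones, and SDs are over the 3 arrays of a strain. Precision is limited by the number of arrays.

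A set of 39 gene lists (complexes, pathways, regulons, cell cycle phases, stress responses, gene families and the marker genes) was fixed before the data were examined. Each list with at least 4 measured genes was tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and with fry; fry asks whether a list's genes move one way on balance and does not compare them with other genes. No list call of camera held with an estimated correlation, with a smallest adjusted p of 0.542 for strain and 0.348 for time, while fry called 16 lists for strain and 0 for time. The 16 are 10 of the 12 that camera called, all but mitochondrial ribosomal proteins and PAU, and 6 others: SAGA, the galactose regulon, glycolysis, drug resistance, hexose transport and zinc and copper. Calls of list members are given over all tested genes and adjusted over the list alone.

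The genes to be named were also fixed in advance: TRA1; the 10 largest rises and 10 largest falls among genes past the strain test with 1 direction at all 3 times; for each list that passed camera or held at least 3 called genes, up to 4 members with the smallest p; for time, up to 6 rises and 6 falls and 3 members per called list; for the slope difference, the 5 with the smallest p each way where none passed; and the 6 marker genes of the strains. Named outside this rule, after their values were seen, were SPT3, TTI1, TTI2, RPL15B, RPS14B, UBI4, FUS3, MSG5, ERG27, COS111, GAL11, NUT2, HTB1, SAG1 and MF(ALPHA)1. The same holds in the closing section for the genes of the lysine, Leu3 and ribosomal RNA sets and of probe sets that name several genes.

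The number in each array's title marks its time, so arrays with the same number share a time point; this pairing comes from the labels. Deviations from the strain means correlated between same-time arrays with r across genes of 0.31 at 60 min, 0.0656 at 90 min and 0.33 at 120 min. The strain test without this block was the main one, and the fit with the time point as a block was run as an alternative.

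Alternatives were the time point as a block or as a linear covariate, quantile normalization over the tested genes, centring on array medians, leaving out genes with means under the lower quartile (5.05) or those under the mouse control probe sets, moderation with a trend and robust settings, all probe sets as rows, each array or time left out, other thresholds, log2 of minutes, time as a factor, no genotype term, camera on ranks, and, chosen after seeing the data, protein-coding genes only and plain _at probe sets only. The background level is the 95th percentile of the means of 4 mouse control probe sets, 3.92. Those means ran from 2.53 to 3.93, so the level is close to that of the brightest set. A value called under the mouse controls lies under 3.92 and can still lie above other mouse sets. That the mouse sets and not the bacterial spikes serve here was settled after their values were seen.

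The scripts were tested on 20 simulated data sets of 5551 genes with 200 changed genes each. The noise was normal and independent between genes and arrays, with the moderated variances of the fits. The shares below hold for that setting. They do not cover correlated genes or arrays, or the larger share of genes called in these data. The strain test recovered 69.9% of 1.41-fold, 99.6% of 2-fold and 100% of 4-fold changes, with 5.25% false genes among its calls. The time test recovered 62.1%, 99.8% and 100%, with 6.26% false, and the test of the slope difference 2.46%, 51.6% and 99.6%, with 7.49% false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.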

Results

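Messenger RNA levels were measured in 2 strains of the budding yeast Saccharomyces cerevisiae after a shift from 30 to 37 °C. Tra1 is a large protein of the phosphatidylinositol 3-kinase-related family and a shared subunit of the SAGA and NuA4 coactivator complexes, where it is contacted by transcriptional activators. In both strains the chromosomal TRA1 gene was replaced with HIS3, and a centromeric LEU2 plasmid supplied either wild-type TRA1 or tra1-2ts, a temperature-sensitive allele. Cells were grown in rich medium (YPD), and RNA of each strain was hybridized to 1 array at each of 60, 90 and 120 min at 37 °C, which makes 6 arrays, 3 per strain. The deposited values are log2 signals after RMA, the robust multi-array average. The 6 arrays had medians between 6.14 and 6.20 over all 6776 probe sets. Pearson's r across probe sets was 0.992 to 0.996 between arrays of 1 strain and 0.971 to 0.980 between arrays of different strains. The 3 times of a strain stand in for its replicates, and nothing in the labels says whether they came from separate cultures, so p-values measure the spread between these arrays, which includes change over time and may otherwise be technical.

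The first question was which genes differed between the tra1-2ts and the wild-type strain. No array from before the shift was analysed here, so whether a difference was already present then was not tested. A difference between the strains is therefore not by itself a dependence on Tra1. TRA1 mRNA itself was higher in tra1-2ts, at 9.37 ± 0.016 against 8.44 ± 0.30 in wild type (log2, mean ± SD, n = 3 arrays each), a difference of 0.93 with a standard error of 0.14 (1.90-fold, limma adjusted p = 0.00132). The probe set reads mRNA level and does not tell the alleles apart, so it does not check the labels. LEU2, the marker of the same plasmid, was lower in tra1-2ts by 1.06 ± 0.11 (SE; 2.09-fold lower, adjusted p = 0.000246). HIS3, which sits at the disrupted TRA1 locus in both strains, differed by 0.15 ± 0.11 and did not pass the test (adjusted p = 0.287). Of the other markers in the genotype, LYS2 rose by 1.03 ± 0.14, and ADE2 and TRP1 did not pass, with differences of -0.20 and -0.04. The tested URA3 probe set read 3.33 in wild type and 2.79 in tra1-2ts, both under the level of the mouse control probe sets (3.92), while a control probe set for URA3 read 4.30 to 4.70 in wild type and 3.92 to 4.17 in tra1-2ts, a difference of -0.46. Both were lower in tra1-2ts.

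Genes of phosphate uptake and ribosome production were lower in the mutant, and among the largest rises were LYS9 of lysine synthesis and ARO9 and ARO10 of aromatic amino acid breakdown. The largest fall was that of SPL2, which encodes a small regulator of phosphate uptake, from 6.71 ± 0.36 in wild type to 3.32 ± 0.17 in tra1-2ts (mean ± SD, n = 3; 10.4-fold lower). PHO89, a sodium-coupled phosphate transporter, fell 6.55-fold from 9.70 ± 0.21 to 6.99 ± 0.12. The largest rise was that of LYS9, saccharopine dehydrogenase of the lysine pathway, from 7.20 ± 0.10 to 9.69 ± 0.35 (5.63-fold). ARO10, a phenylpyruvate decarboxylase, rose 4.82-fold from 4.45 ± 0.15 to 6.72 ± 0.09. In all, 2251 of 5551 genes, 40.5%, passed the strain test at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 1014 higher and 1237 lower in tra1-2ts, and 2246 of them differed in the same direction at all 3 times.

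Of the 2251 genes, 297 differed by at least 2-fold, 135 higher and 162 lower. The lower set included YGR035C (6.49-fold), AAH1 (adenine deaminase, 4.84-fold), YNL058C (4.78-fold), NCA3 (4.59-fold), RGM1 (4.33-fold), the riboflavin transporter gene MCH5 (3.84-fold), COX19 (3.45-fold), whose product serves the assembly of cytochrome c oxidase, and the glucose-repressed alcohol dehydrogenase gene ADH2 (3.44-fold). The tra1-2ts means of SPL2, YGR035C and COX19, at 3.32, 3.73 and 3.79, and the wild-type mean of SER3, at 3.78, lay under the 3.92 of the mouse control probe sets, so these folds depend on the background. The higher set included DAN1 (3.91-fold), a cell wall mannoprotein of anaerobic cells, ARO9 (3.68-fold), an aromatic aminotransferase, SER3 (3.63-fold), which starts serine synthesis, and COS8 (3.63-fold) of a family of near-identical subtelomeric genes. It also held ribosomal RNA genes, with RDN25-1 3.94-fold, RDN37-1 3.73-fold and RDN18-1 3.70-fold higher, and the snoRNA gene SNR73, 3.70-fold higher. The labelling primes on poly(A) tails, and whether these probe sets read the intended transcripts was not tested. The adjusted p of these 20 genes ran from 2.2e-05 to 0.00129 (limma). The predominance of lower calls turned with the scaling: with each array centred on its median over the tested genes, 1248 genes were higher and 1114 lower. Among protein-coding genes, a subset chosen after seeing the data, 64 were at least 2-fold higher and 162 at least 2-fold lower. With both 90 min arrays left out, 1004 genes passed.

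Most genes of ribosome production were lower in tra1-2ts. Of 91 ribosome biogenesis genes, 79 fell and none rose, with a median difference of -0.69 (1.61-fold lower); adjusted over the list alone, 83 fell. HAS1, an RNA helicase of ribosome assembly, fell by 1.29 ± 0.08 (SE), BUD21 by 1.20 ± 0.11, and the GTPase genes NOG2 and NOG1 by 1.19 ± 0.09 and 1.15 ± 0.09. Subunit genes of RNA polymerases I and III moved with them: 15 of 20 fell and none rose (16 fell adjusted over the list alone), with a median of -0.62. Among these, RPA135, the second-largest subunit of RNA polymerase I, fell by 1.27 ± 0.09, RPA49 by 0.99 ± 0.10, RPA34 by 0.97 ± 0.11 and RPA14 by 0.90 ± 0.09. Of 76 measured genes for cytosolic ribosomal proteins, 48 fell and 2 rose, with a median of -0.49 (51 fell and 2 rose adjusted over the list alone). RPS7B fell 2.62-fold, RPL16A 2.11-fold, RPL36A 2.03-fold and RPL37A 1.67-fold, and RPL15B and RPS14B, the 2 that rose, were 1.76- and 1.39-fold higher. Many of these genes come as pairs of near-identical copies, so the copy a probe set reads is uncertain. In limma's camera test the adjusted p was 5.92e-20 for ribosome biogenesis, 2.2e-06 for the polymerases and 2.19e-10 for the ribosomal proteins, and adjusted p = 0.542 for each of the 3 with an estimated correlation between genes. The fry test gave adjusted p of 0.00667, 0.00535 and 0.00408.

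**Figure D1:**
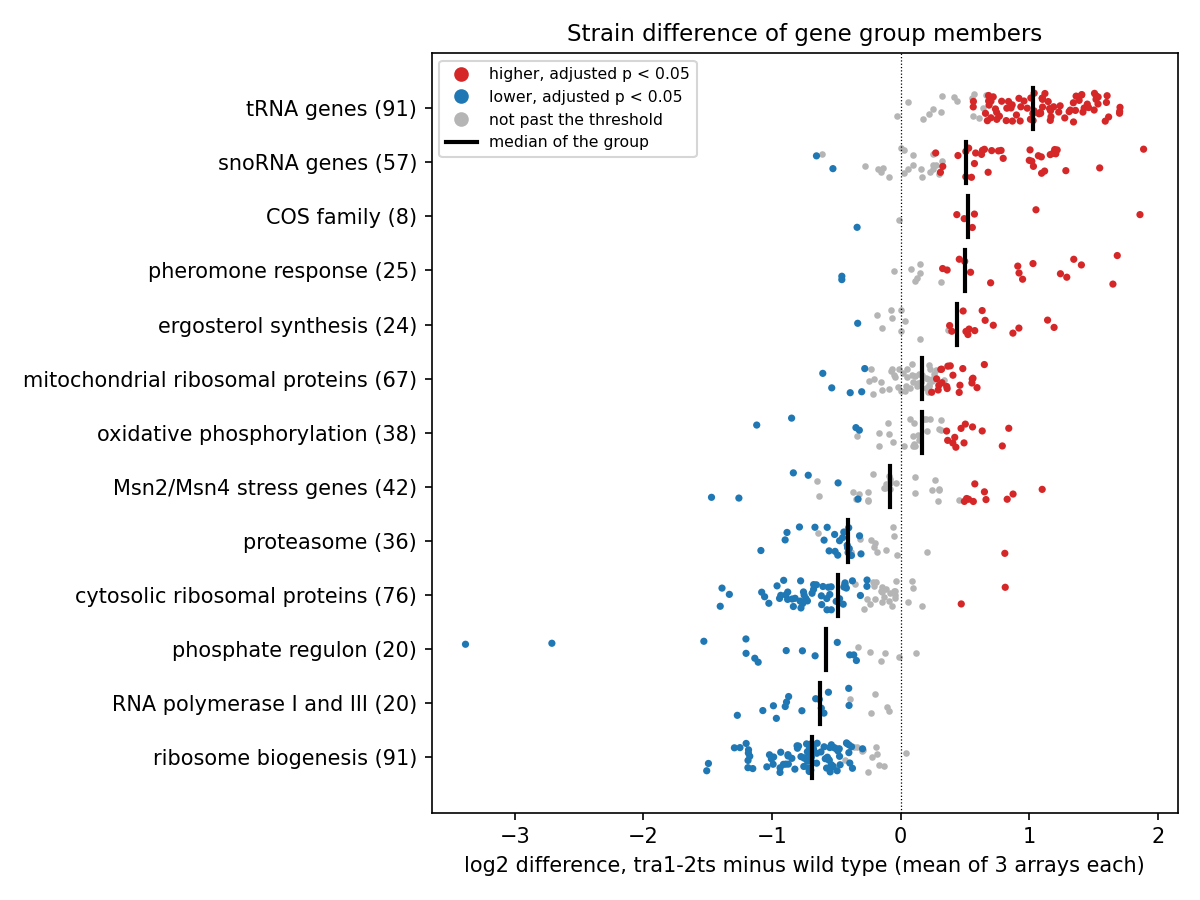
Each point is 1 gene, placed by its log2 difference between the means of 3 tra1-2ts and 3 wild-type arrays; rows are gene groups with the number of measured genes, colours mark genes past an adjusted p of 0.05 (limma) and black bars the group medians. The 91 ribosome biogenesis genes centre on -0.69 and the 91 tRNA genes on 1.03.

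Phosphate and proteasome genes were also lower. Of 20 measured genes of the phosphate regulon list, 14 fell and none rose (15 fell adjusted over the list alone), with a median of -0.58. The list is wider than the genes that Pho4 drives when phosphate is short, and holds PHO4 itself and PHO90. Besides SPL2 and PHO89, the low-affinity transporter gene PHO90 fell by 1.13 ± 0.08 and PHM6 by 1.20 ± 0.11, to 2.86, under the mouse controls. Of 36 proteasome genes, 22 fell and 1 rose (26 and 1 adjusted over the list alone), with a median of -0.41, and PRE10, PRE4, RPN12 and PRE1 were 2.12-, 1.72-, 1.86- and 1.84-fold lower; the member that rose, UBI4 (1.75-fold), encodes polyubiquitin and not a proteasome subunit. Camera gave adjusted p = 2.87e-06 for the phosphate list (adjusted p = 0.542 with an estimated correlation) and 5.29e-06 for the proteasome (adjusted p = 0.564 with an estimated correlation).

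Genes of mating and of sterol synthesis were higher in tra1-2ts. Both strains are of mating type a, and of 25 pheromone response genes 16 rose and 2 fell, also adjusted over the list alone, with a median of 0.50. The genes of the a-factor pheromone rose, MFA1 from 8.11 to 9.76 (3.14-fold) and MFA2 from 11.56 to 12.96 (2.65-fold), and so did those of a-agglutinin, AGA2 2.54-fold and AGA1 2.04-fold, while FUS3, the mitogen-activated kinase of the pathway, and MSG5, its phosphatase, each fell 1.37-fold. Of 24 genes of ergosterol synthesis, 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.44; ERG5 rose 2.29-fold, ERG13 (HMG-CoA synthase) 2.21-fold, ERG3 1.89-fold and ERG25 1.83-fold, and ERG27 fell 1.26-fold. Camera gave adjusted p = 5.29e-06 for pheromone response and 0.000362 for ergosterol, and for both adjusted p = 0.542 with an estimated correlation.

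Rises were also found in mitochondrial, subtelomeric and transcription factor genes. Of 67 genes for mitochondrial ribosomal proteins, 20 rose and 5 fell, also adjusted over the list alone, with a median of 0.17; MRPS8 rose 1.57-fold, MRPS17 1.51-fold and RSM18 1.47-fold, and MRPL17 fell 1.45-fold (camera adjusted p = 0.0123, adjusted p = 0.806 with an estimated correlation; not called by fry, adjusted p = 0.127). Of 38 genes of oxidative phosphorylation, 12 rose and 4 fell (14 and 4 adjusted over the list alone), with a median of 0.16. ATP7 and QCR9 rose 1.79- and 1.73-fold, while COX5B, the hypoxic isoform of a cytochrome oxidase subunit, and INH1, an inhibitor of ATP synthase, fell 2.17- and 1.80-fold. Of 35 TFIID and Mediator subunit genes 11 rose and 2 fell, also adjusted over the list alone, with a median of 0.11; TAF2 rose 1.76-fold, MED4 1.38-fold, SRB5 1.34-fold and MED6 by 0.68 on the log2 scale, and GAL11 fell 1.23-fold. NUT2, the other that fell, had both means under the mouse controls (3.06 and 2.76). Camera gave adjusted p = 0.0353 for oxidative phosphorylation and 0.0445 for TFIID and Mediator, and adjusted p = 0.542 for both with an estimated correlation; with the time point as a paired block the camera values became 0.051 and 0.0611. Single arrays also decided these calls: the adjusted p for oxidative phosphorylation was 0.0664 without the wild-type 120 min array and 0.0574 without the tra1-2ts 60 min array, and for TFIID and Mediator it was 0.0659, 0.0701 and 0.0686 without the wild-type 60 min, the wild-type 120 min and the tra1-2ts 60 min array. Of 8 genes with a COS name 6 rose and 1 fell, also adjusted over the list alone, with a median of 0.53. COS7, COS4 and COS9 were 2.07-, 1.49- and 1.41-fold higher (camera adjusted p = 0.0123 for the list, adjusted p = 0.542 with an estimated correlation). COS111, the one that fell, had both means under the mouse controls (2.44 and 2.11). The list was taken by name alone, and whether COS111 belongs to the subtelomeric family was not checked. Of 10 genes of the PAU family of seripauperins 5 rose and none fell, also adjusted over the list alone, with a median of 0.26, PAU13 1.40-fold, PAU4 1.35-fold, PAU10 1.29-fold and PAU3 1.21-fold (camera adjusted p = 0.0353, adjusted p = 0.806 with an estimated correlation; 0.118 without the wild-type 90 min array and 0.0547 without the tra1-2ts 120 min array), and fry did not call the list (adjusted p = 0.0502). Probe sets of both subtelomeric families share sequence between copies.

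Genes of the complexes that hold Tra1 and of the galactose regulon, a classical target of SAGA, passed the test in both directions. The cells were grown in YPD, so induction of the regulon by galactose was not measured here. Of 17 measured SAGA subunit genes 4 rose and 1 fell, also adjusted over the list alone: ADA2, SPT7 and SPT20 were 1.65-, 1.55- and 1.37-fold higher and SGF29 1.32-fold lower, with SPT3 1.29-fold higher. Of 12 NuA4 genes 1 rose, the catalytic ESA1 (1.42-fold), and 3 fell, EAF1 (2.32-fold), EAF5 (1.20-fold) and EPL1, whose means both lay under the mouse controls (3.67 and 3.32), with 1 and 2 adjusted over the list alone. Of 8 genes of other kinases of the family and their TTT chaperone 2 rose, TTI2 (1.33-fold) and TTI1 (1.21-fold), and none fell (1 and 0 adjusted over the list alone). With the time point as a paired block the calls of EAF5 (adjusted p = 0.0491) and TTI1 (0.0461) ended, at 0.0614 and 0.0551. In the galactose regulon, 1 of 10 genes rose, GAL80 (1.22-fold), and 3 fell, MTH1 (1.67-fold), GAL10 (1.43-fold, from 3.92 to 3.41, at the level of the mouse controls) and GAL3 (1.21-fold), also adjusted over the list alone. Camera gave adjusted p of 0.231 for SAGA, 0.97 for NuA4, 0.333 for the other kinases and 0.553 for the galactose regulon. The fry test called SAGA higher (adjusted p = 0.0405, 13 of 17 differences positive, median 0.05) and the galactose regulon lower (0.0266, 6 of 10 negative, median -0.07), and not NuA4 (0.276) or the other kinases (0.121). The SAGA median was 0.25, 0.11 and -0.08 at 60, 90 and 120 min, so its direction did not hold at 120 min.

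Stress and amino acid lists held large changes in both directions. Over all 5551 tested genes 1014 rose and 1237 fell (40.55% called), and the member counts of every list are to be read against that share. A count near it does not set a list apart. Of 42 genes driven by the general stress factors Msn2 and Msn4, 10 rose and 6 fell, also adjusted over the list alone, with a median of -0.08; the protease gene PRB1 rose 2.15-fold and XBP1 1.78-fold, and SOL4 and GAC1 fell 2.77- and 2.39-fold. Of 30 heat-shock chaperone genes 8 rose and 3 fell (7 and 3 adjusted over the list alone), with BTN2 3.20-fold, HSP42 2.22-fold, the Hsp40 gene SIS1 2.03-fold and HSP31 1.56-fold higher. Of 45 amino acid genes driven by Gcn4, 15 rose and 10 fell (16 and 10 adjusted over the list alone); LYS9, LYS1 (3.59-fold) and LYS21 (2.20-fold) rose and LEU9 fell 2.53-fold. Of 25 methionine genes 3 rose and 6 fell, also adjusted over the list alone, with SAM2 1.99-fold higher and the transporter gene MMP1 2.72-fold, MUP3 1.77-fold and MET8 1.62-fold lower. Of 18 genes of purine synthesis 5 rose and 9 fell (5 and 10 adjusted over the list alone), with GCV2 1.80-fold higher and ADE1 2.13-fold, IMD4 2.02-fold and IMD2 1.89-fold lower. None of these 5 lists passed camera, with adjusted p from 0.258 for purine synthesis to 0.919 for methionine. For the chaperones the median was -0.05 and the mean 0.18, and for the NuA4 genes the median was 0.10 and the mean -0.03, so those lists have no single direction. Camera's direction was up for the chaperones and for Msn2 and Msn4 (mean -0.01), against their medians.

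Nutrient transport and carbon metabolism lists held changes in both directions. Of 17 glycolysis and fermentation genes 7 rose and 1 fell (7 and 2 adjusted over the list alone), PGI1 1.41-fold, PFK2 1.32-fold and PDC1 1.29-fold up, ADH2 down (camera adjusted p = 0.0988). Of 25 genes of the tricarboxylic acid and glyoxylate cycles and gluconeogenesis 3 rose and 5 fell, also adjusted over the list alone: CIT2 rose 1.83-fold, and IDP2, PCK1 and MDH1 fell 2.87-, 2.42- and 1.92-fold. The zinc transporter gene ZRT2 fell 3.42-fold and ZRT1 1.51-fold, within a zinc and copper list of 13 in which 2 rose and 4 fell (3 and 4 adjusted over the list alone). HXT4, a hexose transporter gene, fell 2.21-fold, and 1 of 12 hexose transport genes rose and 2 fell, also adjusted over the list alone. Among 15 drug resistance genes under Pdr1 and Pdr3, 2 rose and 6 fell (3 and 6 adjusted over the list alone), TPO4 up 2.29-fold and RSB1 (to 3.63, under the mouse controls), RTA1 and SNQ2 down 2.53-, 2.06- and 1.66-fold. Of 26 iron genes 5 rose and 5 fell (5 and 6 adjusted over the list alone), with ARN1 up 1.75-fold and FET4, ISU1 and ENB1 down 2.03-, 1.84- and 1.53-fold. Of 24 nitrogen catabolite genes 6 rose and 3 fell, also adjusted over the list alone, with GLN3 (from 3.86, under the mouse controls) and MEP2 up 1.36- and 1.34-fold and GDH2 and AVT1 down 1.89- and 1.36-fold. Camera adjusted p ran from 0.231 for the drug resistance list to 0.973 for iron over these 6 lists after glycolysis. The fry test called 4 of the 7 lists, glycolysis upward (adjusted p = 0.0427; median 0.20, 13 of 17 differences positive) and 3 downward. These were drug resistance (0.00346; median -0.16, 11 of 15 negative), hexose transport (0.00535; median -0.05, 7 of 12 negative, and 0.02 at 90 min) and zinc and copper (0.0264; median -0.07, 7 of 13 negative).

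Cell cycle, cell wall and damage lists were mixed as well. Of 35 G1/S genes 4 rose and 9 fell, also adjusted over the list alone: the cyclin genes PCL1 and CLN1 rose 2.97- and 2.11-fold, and PRI2 and DPB2 of DNA replication fell 1.55-fold each. Of 25 G2/M genes 5 rose and 5 fell, also adjusted over the list alone, with CHS2 and SWI5 (to 3.42, under the mouse controls) down 1.58- and 1.59-fold and WSC4 and MOB1 up 1.92- and 1.93-fold. Of 26 M/G1 genes 4 rose and 1 fell, also adjusted over the list alone, with CHS1 up 2.40-fold, MCM4 1.76-fold and ASH1 1.55-fold and PRY3 down 1.66-fold. Of 38 cell wall genes 12 rose and 5 fell (13 and 5 adjusted over the list alone), SCW10 up 2.72-fold, TIR1 up 2.13-fold, CWP1 down 2.04-fold and CHS7 down 1.72-fold. Of 18 DNA damage genes 3 rose and 5 fell, also adjusted over the list alone, with RNR4 up 2.12-fold, HUG1 up 2.08-fold and RAD2 and RAD7 down 1.92- and 1.61-fold. Of 23 oxidative stress genes 6 rose and 4 fell (7 and 4 adjusted over the list alone), with SOD1 up 1.32-fold and GRE2 down 2.37-fold. Of 28 genes of the endoplasmic reticulum 6 rose and 3 fell (5 and 3 adjusted over the list alone), with INO1 up 1.66-fold, from 3.79, under the mouse controls, and ERO1 down 1.58-fold. Of 36 meiotic genes 6 rose and none fell (3 and 0 adjusted over the list alone), SPO22 by 1.64-fold, from 3.40, under the mouse controls, and NDT80 by 1.41-fold; of 5 measured histone genes 1 rose, HTB1 (1.30-fold), and 1 fell, the linker histone gene HHO1 (1.81-fold), also adjusted over the list alone. Of 4 genes specific to the opposite mating type 2 rose, SAG1 (1.41-fold) and MF(ALPHA)1 (1.36-fold), and none fell, also adjusted over the list alone. Camera adjusted p for these 10 groups and for the marker genes lay between 0.131 and 0.973, and none passed. Median and mean differed in sign for the histones (0.10 and -0.13), the tricarboxylic acid cycle (0.02 and -0.12), M/G1 (-0.03 and 0.03), G2/M (-0.04 and 0.0015) and iron (0.03 and -0.03).

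At single times, where each difference rests on 1 array per strain and has no error, 101 genes were at least 2-fold higher and 146 lower in tra1-2ts at 60 min, 182 and 242 at 90 min, and 164 and 207 at 120 min. At all 3 times, 72 genes were at least 2-fold higher and 91 at least 2-fold lower. Across genes, which are not independent replicates, the differences at 60 and 90 min had a Pearson's r of 0.836, those at 60 and 120 min 0.801, and those at 90 and 120 min 0.866; each time has its own wild-type array, so no array is shared. The median of the ribosome biogenesis genes was -0.56, -0.81 and -0.64 at 60, 90 and 120 min, that of the phosphate regulon -0.45, -0.75 and -0.50, and that of pheromone response 0.46, 0.43 and 0.59.

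**Figure D2:**
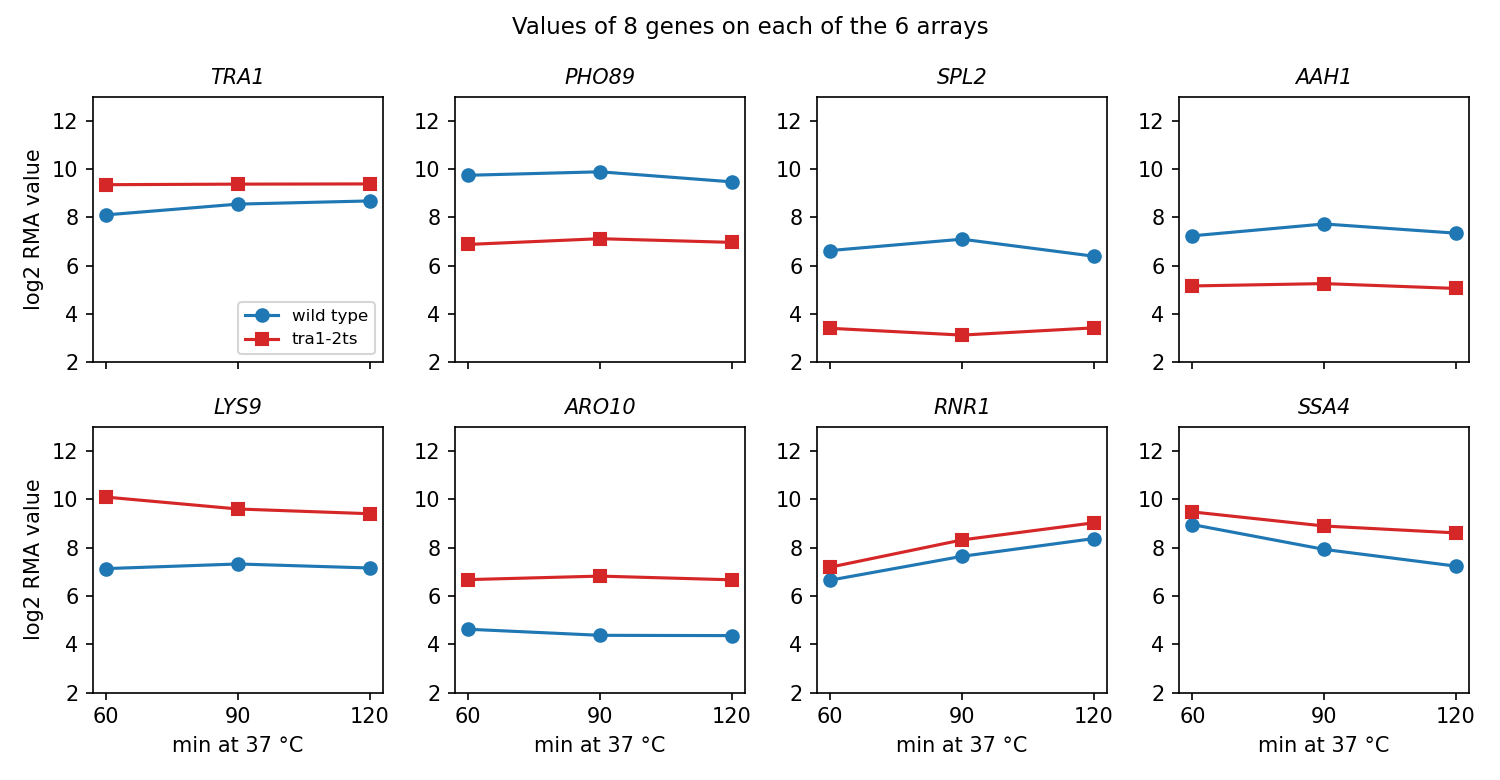
Log2 RMA value of 8 genes against minutes at 37 °C, with 1 point per array (circles, wild type; squares, tra1-2ts; no error bars, 1 array per strain and time). PHO89, SPL2 and AAH1 lie lower and TRA1, LYS9 and ARO10 higher in tra1-2ts at all 3 times, while RNR1 rises and SSA4 declines with time in both strains.

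The second question was how expression moved between 60 and 120 min at 37 °C in both strains. Few genes passed the test; those that rose included genes of the start of the cell cycle, and those that fell included genes of heat shock and of cell separation. RNR1, the large subunit of ribonucleotide reductase, rose by 1.78 ± 0.12 on the log2 scale per 60 min (SE; 3.43-fold, limma adjusted p = 0.00267), with slopes of 1.72 in wild type and 1.83 in tra1-2ts. The histone gene HTB2 rose 2.53-fold, TOS6 2.12-fold and the G1 cyclin gene PCL1 1.91-fold. RGI1, a gene of respiratory growth, fell 3.31-fold (-1.73 ± 0.18), REE1 2.61-fold, the stress-inducible Hsp70 gene SSA4 2.45-fold, YBR053C 2.14-fold, the daughter-cell glucanase gene DSE4 2.07-fold and AIM17 1.92-fold. The test called 18 genes, 4 rising and 14 falling, and 897 had an unadjusted p under 0.05, where 278 would be expected by chance.

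Of 35 G1/S genes 34 had positive slopes, with a median of 0.41 per 60 min; 2 rose over all genes and 22 adjusted over the list alone. MCD1, at 0.65 ± 0.10, missed the threshold over all genes (adjusted p = 0.0554). Of 26 M/G1 genes 23 had negative slopes, with a median of -0.34; 3 fell over all genes, DSE4, the chitinase gene CTS1 (1.70-fold) and EGT2 (1.79-fold), and 14 fell adjusted over the list alone. Of 30 chaperone genes 21 had negative slopes, with a median of -0.32; SSA4 and CPR6 (1.74-fold) fell over all genes, and 14 fell adjusted over the list alone. Of 42 Msn2 and Msn4 genes 35 had negative slopes, with a median of -0.31; none was called over all genes and 9 fell adjusted over the list alone, and HXK1 had a slope of -0.93 ± 0.19 (adjusted p = 0.0739). Camera called these 4 lists with adjusted p of 3.17e-17, 1.79e-09, 1.67e-06 and 1.99e-06. With an estimated correlation the adjusted p was 0.348 for G1/S and M/G1, 0.554 for the chaperones and 0.817 for Msn2 and Msn4, and fry called none of the 39 lists.

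Camera called 6 other lists over time, each with adjusted p = 0.817 with an estimated correlation. Upward calls were ribosome biogenesis (median slope 0.13, 23 of 91 slopes negative) and the 5 measured histone genes (0.24), with adjusted p of 0.000157 and 0.00337. In ribosome biogenesis no member was called, over all genes or adjusted over the list alone, and UTP18, UTP15 and NOP12 had slopes of 0.38, 0.36 and -0.44. Of the histone genes HTB2 alone was called, also adjusted over the list alone, with HHO1 and HTZ1 at 0.29 and 0.24. Downward calls were the list of the tricarboxylic acid and glyoxylate cycles (median slope -0.19), in which FUM1 fell 1.91-fold and 7 genes fell and 3 rose adjusted over the list alone, the proteasome (-0.12, none called), cell wall genes (-0.11; 4 fell adjusted over the list alone) and purine synthesis (-0.16; 3 fell adjusted over the list alone), with adjusted p of 0.017, 0.0184, 0.0241 and 0.0492. Without the wild-type 60 min array 6 of the 10 lists were no longer called, Msn2 and Msn4 (adjusted p = 0.191), the tricarboxylic acid cycle (0.54), cell wall (0.847), proteasome (0.0868), purine synthesis (0.0876) and ribosome biogenesis (0.957), whose median slope became -0.015. The proteasome call was also lost without the wild-type 120 min array (0.565), the histone call without that array (0.0578), and the purine call without the wild-type 120 min (0.324), the wild-type 90 min (0.0672) or the tra1-2ts 90 min array (0.0581).

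The time calls rested on few arrays. Without 1 array the count of 18 genes became 0 without either 60 min array, 1 without the wild-type 120 min or the tra1-2ts 90 min array, 6 without the tra1-2ts 120 min array and 12 without the wild-type 90 min array. Across genes, the slopes of the 2 strains had a Pearson's r of 0.364. Arrays at 30 °C were not analysed here, so these slopes describe change after 60 min at 37 °C and not the response to the shift itself.

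**Figure D3:**
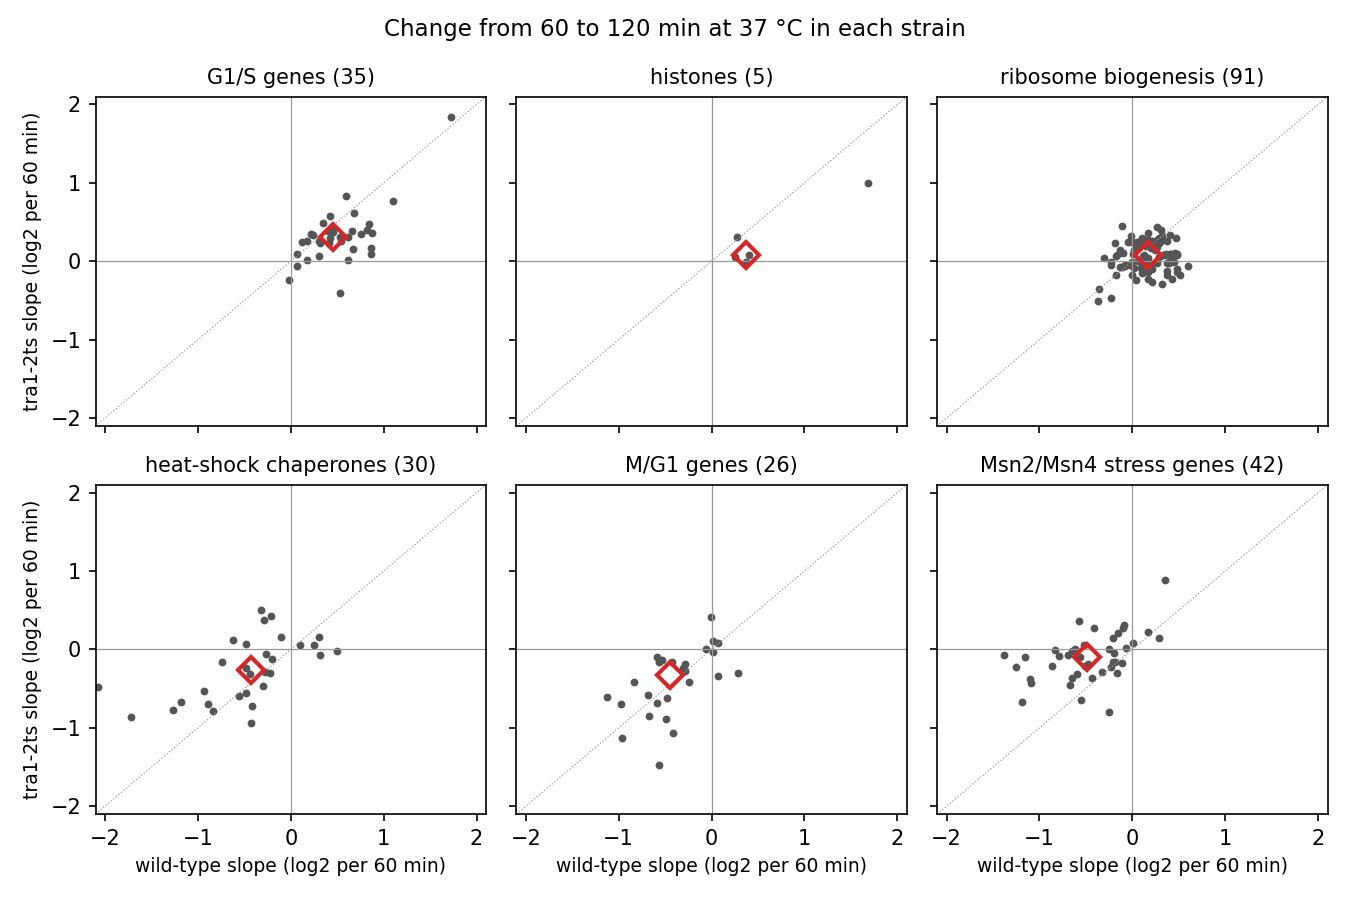
Slope of each gene in tra1-2ts against its slope in wild type, in log2 units per 60 min between 60 and 120 min at 37 °C; grey points are genes, open diamonds the medians, dotted lines equal slopes, and the number of genes is in brackets. The G1/S medians are 0.46 in wild type and 0.30 in tra1-2ts, and the Msn2/Msn4 medians -0.49 and -0.09.

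The third question was whether the difference between the strains itself changed with time. No gene passed this test (limma, smallest adjusted p = 0.67), and 392 genes had an unadjusted p under 0.05, where 278 would be expected by chance. Of the 5 genes each way with the smallest unadjusted p, none of which passed, the protease gene BAR1 had a slope per 60 min of -1.02 in wild type and 0.09 in tra1-2ts, SNO1 -0.53 and 0.91, RDN37-1 -0.02 and 1.39, YHR022C -0.48 and 1.26 and YNCD0021C -0.55 and 0.78. In the other direction DSE2 had -0.57 in wild type and -1.48 in tra1-2ts, MNN1 0.74 and -0.20, YIL060W 1.13 and -0.31, YER187W 0.46 and -0.61 and YER121W 0.55 and -0.49. The fit leaves 2 residual degrees of freedom. Without 1 wild-type array it called 210 genes (120 min left out), 89 (60 min) or 83 (90 min), and without any 1 of the tra1-2ts arrays it called 0.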

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

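The list test of the slope difference was chosen only after the data had been seen. By camera, 6 of the 39 lists differed between the strains in their slope over time, in limma's fit of a slope per strain, each with 0 members past the gene test. The Msn2 and Msn4 stress genes had the largest median difference, 0.35 per 60 min (tra1-2ts minus wild type, positive in 37 of 42 genes; adjusted p = 7e-08), with median slopes of -0.49 in wild type and -0.09 in tra1-2ts. The other 5 were the cytosolic ribosomal proteins at -0.12 (adjusted p = 0.0111), G1/S genes at -0.17 (0.0111), mitochondrial ribosomal proteins at -0.15 (0.0111), methionine genes at 0.15 (0.0111) and pheromone response at 0.16 (0.0121). With an estimated correlation, adjusted p = 0.945 for each of the 6, and fry called 0 lists.

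Probe sets outside the tested genes also differed between the strains. Of the 925 probe sets with no gene name 205 passed the strain test (limma, adjusted p under 0.05), 156 higher and 49 lower in tra1-2ts, and of the 183 with several gene names 101 passed, 58 higher and 43 lower. Control probe sets were left out of the ranking of single sets, and one of them, for 18S rRNA, was 1.86 higher in tra1-2ts. Among the other unnamed sets, probe set 11226_at had the largest rise, 1.59 ± 0.094 (SE), higher in 3 of 3 arrays. The largest fall was that of probe set 5626_at, -1.97 ± 0.208, lower in 3 of 3. No explanation was tested for these.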

How the results depend on the processing

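The fits on protein-coding genes and on plain probe sets were chosen after seeing the data. The strain count of 2251 genes stayed within 1.5 times under all settings but 1: with both 90 min arrays left out it was 1004 (996 of them among the 2251), a fit with 4 arrays; without a single array it ran from 1561 to 2214. No called gene changed direction under any setting that keeps gene names. With the time point as a paired block, 2520 genes, 298 at 2-fold and 10 lists were called, TRA1 differed by 0.93, and the block ended 2 list calls, oxidative phosphorylation and TFIID with Mediator. Over all genes, centring and quantile normalization moved the median difference to 0.05 and 0.02, and the median of each called list kept its sign under both. The 167 named genes past the threshold kept their call in 2856 of 2958 refits and lost it in 102, 36 of these without the 90 min arrays. The 12 strain lists became 0 and the 10 time lists 0 with an estimated correlation, and the time lists 0 with fry. The 18 time genes became 125 at an adjusted p of 0.10, 11 without genes under the lower quartile of means, 7 for 120 against 60 min, 0 with no genotype term, whose spread then holds the strain difference, and 0 to 12 without single arrays. The slope-difference count of 0 ran from 0 to 210 without single arrays; without a wild-type array its spread rests on the tra1-2ts arrays alone. At single times, 921, 1256 and 1166 genes differed at least 1.5-fold and 25, 86 and 59 at least 3-fold at 60, 90 and 120 min. Where signals lie near the mouse controls (3.92), folds are limited by the background. The causes of the other shifts were not tested.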

Other observations

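The tests of plasmid copy number, of a full stress response, of brightness for the ribosome biogenesis genes, of whole chromosomes, of tRNA against snoRNA genes on plain probe sets, of Gcn4 targets outside the lysine pathway and of fry over other splits were chosen only after the result had been seen. Genes of non-coding RNA stood out on the higher side. Of 91 tRNA genes 76 rose in tra1-2ts and none fell (limma, adjusted p under 0.05), with a median of 1.03 (2.04-fold), and 90 of 91 differences were positive. Of 57 snoRNA genes 34 rose and 2 fell, with a median of 0.51, and all 4 measured snRNA genes of the spliceosome rose, with a median of 0.81. All 4 rRNA genes rose: RDN18-1 by 1.89 ± 0.28 (SE), RDN25-1 by 1.98 ± 0.30, RDN5-1 by 1.56 ± 0.24 and RDN5-3 by 0.98 ± 0.21. A control probe set for 18S rRNA was 1.86 higher on average and higher at all 3 times, and one for 25S rRNA was 1.02 higher on average, but at 60 min it read 8.69 in tra1-2ts and 8.91 in wild type. The labelling primes on poly(A) tails, and whether these probe sets read the intended transcripts was not tested. The medians of the tRNA genes were 0.98, 1.08 and 1.02 at 60, 90 and 120 min.

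Several genes of lysine synthesis rose. This set was put together after LYS9, LYS1 and LYS21 had been seen among the rises, and it was not tested as a list. Of its 8 measured genes 7 rose and none fell, with a median of 0.89: LYS9 5.63-fold, LYS1 3.59-fold, LYS21 2.20-fold, LYS2 2.05-fold, LYS4 1.68-fold, ARO8 1.46-fold and LYS5 1.30-fold, while LYS12, at 0.43 ± 0.15, missed the threshold (adjusted p = 0.051, limma). ARO9 and ARO10, the targets of the activator Aro80, rose 3.68- and 4.82-fold. The 40 measured Gcn4 targets outside the lysine pathway had a median of -0.086, with a 95% bootstrap interval over genes of -0.21 to 0.13. The interval argues against a median rise of these targets by the 0.3 that the test asked for, though it treats genes as independent. The test itself came out undecided, because it asked the median to lie under 0.3 by more than the SD of the members. The genes moved both ways, with an SD of 0.57, so whether higher Gcn4 activity raised part of them stays open.

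For the tRNA genes, the brightness of the probe sets does not account for the rise: their median of 1.03 lay above the highest of 10000 lists of protein-coding genes matched on mean level, 0.17. A common rise of all RNA without poly(A) tails relative to mRNA, by 1 factor, stays open. The tRNA median exceeded the snoRNA median by 0.523 (95% bootstrap interval 0.31 to 0.79), but 88 of the 91 tRNA genes have probe sets without the plain suffix. On plain probe sets, 3 tRNA and 53 snoRNA genes, the difference was -0.13 (-0.48 to 0.77). Cross-hybridization between tRNA copies stays open as well, because only 3 tRNA genes have a plain probe set; their median was 0.418 with an interval from 0.18, against a bound of 0.2 set in advance. Whether RNA classes rose by different amounts was compared for tRNA and snoRNA genes only, and the kinds of probe set leave it undecided. An effect of Tra1 as the cause of these rises was not tested.

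TRA1 mRNA was higher and LEU2 mRNA lower although both genes sit on the same plasmid. Plasmid copy number as the whole cause is argued against, since it would move both the same way and LEU2 differed by -1.06 ± 0.11. Lower expression of the targets of Leu3, the activator of LEU2, may account for the LEU2 part: the 7 other targets had a median of -0.201, but the bootstrap interval, -0.35 to 0.50, leaves this open. LEU4 and LEU1 rose 1.89- and 1.41-fold, and ILV2 and MAE1 fell 1.49- and 1.27-fold. A change in TRA1 transcription or mRNA stability in the mutant was not tested.

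The fall of ribosome biogenesis and ribosomal protein genes is one arm of the general environmental stress response of yeast, in which Msn2 and Msn4 targets rise. Brightness of the probe sets is argued against as the source of the fall, since the ribosome biogenesis median of -0.685 lay below the lowest of 10000 lists matched on mean level, -0.26. For a full stress response the test asked for a median of at least 0.34 in the Msn2 and Msn4 list. The median was -0.0795, with a 95% bootstrap interval over genes of -0.17 to 0.26. The interval argues against a list median 0.34 higher in tra1-2ts, though it treats genes as independent. The test itself came out undecided, because it asked the median to lie under 0.34 by more than the SD of the members. Both strains were at 37 °C, so the values compare the strains and do not show whether the response was on in either. In the list 18 genes were higher and 24 lower, with an SD of 0.55, so a response of part of the list stays open. Its median difference was -0.28, 0.03 and 0.11 at 60, 90 and 120 min. Slower growth of the mutant at 37 °C and a direct loss of coactivator function stay open as untested explanations.

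The hypothesis that genes next to telomeres shift was tested with the 10 outermost measured protein-coding genes of each of 32 chromosome arms. Their median of 0.0301 lay within the central 95% of matched lists, -0.05 to 0.04. Of the 320 genes 64 rose (20%, against 16.6% of coding genes) and 68 fell (21.2%, against 22.9%). This leaves the hypothesis open, because probe sets that name several genes were left out of the test. Those of families with subtelomeric members went both ways. The differences were positive for the 14 sets of YRF1 (0.09 to 0.68; 6 called higher), the 4 of COS (0.48 to 0.98; all called) and the 12 of PAU (0.03 to 0.83; 9 called), 3 families picked after their values were seen. They were negative, and called, for PHO11 with PHO12 (-1.87), SNZ2 with SNZ3 (-0.45), MAL12 with MAL32 (-0.41), the IMA genes (-0.29) and YHR214W with YAR066W (-0.71). These too were picked after their values were seen, without a tally of all subtelomeric sets. Others called were THI5 with THI11, THI12 and THI13 (1.32), MPH2 with MPH3 (0.82) and SOR1 with SOR2 (-0.44). Of all 183 sets with several genes, 58 were called higher and 43 lower. Sets of a family share sequence, so they are not separate genes. A chromosome doubled in a haploid strain, which would raise its genes by about 1, is argued against: the chromosome median farthest from 0, that of chromosome 5, was -0.0813, with an SD of 0.48 over its genes.

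The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2251 genes and the highest of the others 0, and at 2-fold 297 and 0. In each case 1 split, the real one, reached the count. Of the list tests, fry called 16 lists in the real split and at most 0 in another (1 split reached 16). Every other split puts arrays of both strains into each group, so the strain difference enters its residual spread. Counts of 0 for genes and for fry are then nearly fixed in advance and decide nothing. Camera with its preset correlation called 12 lists in the real split and up to 16 in others, with 5 of the 10 splits at 12 or more. Among the splits that, like the real one, put the 2 arrays of each time into different groups, the highest other camera count was 11.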
